A study of Homo sapiens with 6 samples.

How the data were processed

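Gene expression was measured on 6 Agilent human arrays with 2 colours, 3 for C5LM2 over C5 and 3 for L3.6 over FG, as total RNA extracted with Trizol from cells grown without treatment, per the labels' protocols. The poorly metastatic line (C5 or FG) carried Cy3 and the highly metastatic line (C5LM2 or L3.6) carried Cy5 on every array, per the labels. No dyes were swapped, so a gene-specific dye effect is part of each ratio, and one of equal size cancels in the difference between the pairs. Per the file headers, the intensity values of each spot were extracted by the authors with Agilent Feature Extraction 9.5.3.1, and the probe coordinates are those of hg18. Mean intensity and local median background are deposited per spot and channel, without normalisation. The log10 ratio of Cy5 over Cy3, and its p-value from the error model of a single array, were made by the scanner software from background-subtracted, dye-normalised signals, per the file headers. The authors' series table holds that same log10 ratio: 45015 of 45015 values per array equal the scanner files' within a relative tolerance of 0.005, with a median of 0 on each array, so that its scale, centring and direction are known.

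The authors' deposited lists hold, per array, spots whose Cy5 over Cy3 ratio was at least 10-fold, and on 3 of 6 arrays they are 1 spot short of all such spots. A column of these lists named an inverse fold equals 10 to the power of minus the log ratio's error on 5 of 6 arrays, so it was not used. The deposited p-values of single arrays were not used either.

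Background was corrected by normexp with an offset of 50 on mean and local background intensities, and each array was normalised by loess with control spots at weight 0. Control spots and spots marked as outliers were left out, and spots of one probe were averaged. Of 41000 distinct probes, 28696 matched a table of current gene names: 25398 by accession, 2510 by symbol and 788 by an older symbol. The others kept the array's own name, and some of those had been turned into dates by a spreadsheet. For each gene the probe with the highest mean intensity over all arrays was kept, which left 30140 genes. A gene was tested in a pair if well above background on all 3 arrays in at least one line, which held for 19013 genes in the C5 pair and 20047 in the FG pair. For the difference any of the 4 lines sufficed, for 21064 genes. XIST and Y-linked genes were left out throughout.

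Replicates were compared before averaging, over 184 probes with several spots. Arrays of one pair on one slide differed by 1.23 (C5LM2 over C5, replicates 2 and 3) and 0.980 (L3.6 over FG, replicates 1 and 2) times the noise expected from the spots. Arrays on different slides differed by 47.4 to 49.5 times it in the C5 pair and by 5.96 to 6.17 times it in the FG pair. Each couple on one slide was therefore averaged and counted as 1 sample, which left 4 samples, 2 per pair. The design fixed before the data were examined had the 6 arrays as separate replicates. The averaging was chosen after the data, and the counts under the fixed design, were seen, and it lowered the counts. The other settings were kept as fixed. A version that estimated the variance prior from tested genes alone was also run and then set aside, because all genes on the array had been used first. The effect of these choices is given with the other alternatives.

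Log2 ratios were fitted with limma 3.58.1 in R 4.3.3, with one mean per pair and one spread shared by both pairs, followed by eBayes with a trend by mean intensity. The fit had 2 residual degrees of freedom per gene and a prior of 2.25. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, with a threshold of 0.05. The named genes followed a rule fixed in advance. It took genes with a symbol past the threshold, with an absolute log2 ratio or difference of at least 1. All 3 arrays of a pair had to be of one sign. For the difference, the 3 ratios of one pair could not overlap the 3 of the other. Named were the 12 highest and 12 lowest of a pair and the 8 highest and 8 lowest of the difference. To these were added up to 4 members of each described list. For the FG pair 508 genes were eligible, for the difference 122 and for the C5 pair 0, so the C5 genes named were chosen after their values were seen. Gene lists, 39 in number and fixed in advance, were tested with limma's camera at a correlation of 0.01, with camera at an estimated correlation and with fry, where at least 5 members were tested. Of their genes 77 stand in more than one list. The result of one of these lists is not reported here.

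The fit was tested on simulated data with the fitted spread, drawn alike for both pairs, and 50 changed genes per size. The real replicates correlated at r = -0.0248 in the C5 pair and 0.974 in the FG pair. The rates below are therefore those of the shared model and not of either pair. In the FG pair it recovered 6% of 2-fold, 54% of 4-fold and 96% of 16-fold changes, with 11 false calls among 20047 genes. In the C5 pair it recovered 4%, 58% and 96%, with 15 false calls among 19013, and for the difference 2%, 26% and 88%, with 5 among 21064. Of 3 lists shifted by 1 log2 unit in the FG pair, camera with the preset correlation recovered 3, fry 2 and camera with an estimated correlation 0. These lists do not show how the preset correlation fares where the members of a list vary together.

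Alternatives were other background corrections, other normalisations, other filters on dim probes, other variance models, the slide or the replicate number as a block, single slides, and leaving out each array in turn. Random blocks used statmod 1.5.0. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and matrixStats 1.5.0 in R.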

Results

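The series compared 4 human cell lines in 2 pairs, each pair being a poorly metastatic and a highly metastatic line derived from one parent. FG and L3.6 are pancreatic carcinoma lines, FG poorly and L3.6 highly metastatic. C5 is a poorly metastatic subclone and C5LM2 its highly metastatic counterpart, and the labels used here do not give their tissue. The question was which transcripts separate the highly from the poorly metastatic line of a pair. Total RNA of untreated cells was hybridised to Agilent human expression arrays with 45015 spots, with the poorly metastatic line in the Cy3 channel and the highly metastatic line in the Cy5 channel of every array. Each pair had 3 arrays, which limits the precision of every value. Between 60.4% and 70.8% of the spots were well above background in Cy3, and between 66.8% and 82.3% in Cy5. Replicates 1 and 2 of L3.6 over FG, on one slide, differed by 0.980 times the noise between spots of one probe, less than the sampling noise. Replicates 2 and 3 of C5LM2 over C5, on the same slide, differed by 1.23 times that noise, slightly above it. Each of these couples was averaged and counted as 1 sample, so that n = 2 for each pair. All values are log2 ratios of the highly over the poorly metastatic line, and each error is the SD of these 2 replicates. The labels number the replicates without saying that they were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

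L3.6 cells carried 399 genes at a higher level and 391 at a lower level than FG cells, out of 20047 tested. The ranks given here are those of named genes and leave out genes known only by a bound. The highest ratio was that of GDF15, a stress-induced secreted member of the TGF-beta superfamily. It stood at 5.45 ± 0.12 (SD, n = 2), or 43.8-fold (limma adjusted p = 0.0134). The chemokine CXCL11 followed at 5.40 ± 0.08 (SD, n = 2), with FG above background on 1 of 3 arrays. The lowest was SPINK6, a Kazal-type inhibitor of serine proteases, at -7.03 ± 0.31 (SD, n = 2). TGFBI, a secreted matrix protein induced by TGF-beta, stood at -5.84 ± 0.12 (SD, n = 2). All 3 arrays showed the direction of each of these 4 genes, as the rule for naming required.

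The other genes with the highest ratios were DUSP5, a phosphatase that inactivates ERK (5.17), the copper-carrying ferroxidase CP (4.88), ZSCAN18 (4.79, FG above background on 1 of 3 arrays) and HS3ST1, which sulphates heparan chains (4.68). SPINK4 (4.60), the epithelial keratin KRT13 (4.40), the hyaluronan synthase HAS3 (4.34), the trefoil peptide TFF2 (4.30) and NRN1 (4.22) were next. ITM2A was at least 24.2-fold higher, being not well above background in FG. Among the genes with the lowest ratios were SPINK13 (-5.83), the microfibril protein MFAP5 (-5.47), CPS1, the entry enzyme of the urea cycle (-5.36), and the pancreatic secretory protein REG1A (-5.29). The Wnt receptor FZD10 (-4.80), RNF182 (-4.34) and CGA, the common subunit of the glycoprotein hormones (-4.33), were also lower. TPGS2, TMEM204 and the glutaminyl cyclase QPCT were at least 47.9-fold, 44.2-fold and 19.4-fold lower, being not well above background in L3.6. Such a bound sets the bright line against the lowest signal that was well above background in the other channel, and it is open to dye bias. Over these 24 genes the limma adjusted p ran from 0.0123 to 0.0463. The 3 arrays of the pair had one sign for each gene, as the rule required. No second probe of any of them had the opposite sign. The probe of GDF15 lies on chromosome 19 at 18360890 to 18360949 (hg18). Those of SPINK6 (147574671 to 147574730) and SPINK13 (147645895 to 147645954) lie near each other on chromosome 5, where TGFBI was probed at 135427242 to 135427301. Whether the probes fall in coding exons or untranslated regions was not analysed here.

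**Figure D1:**
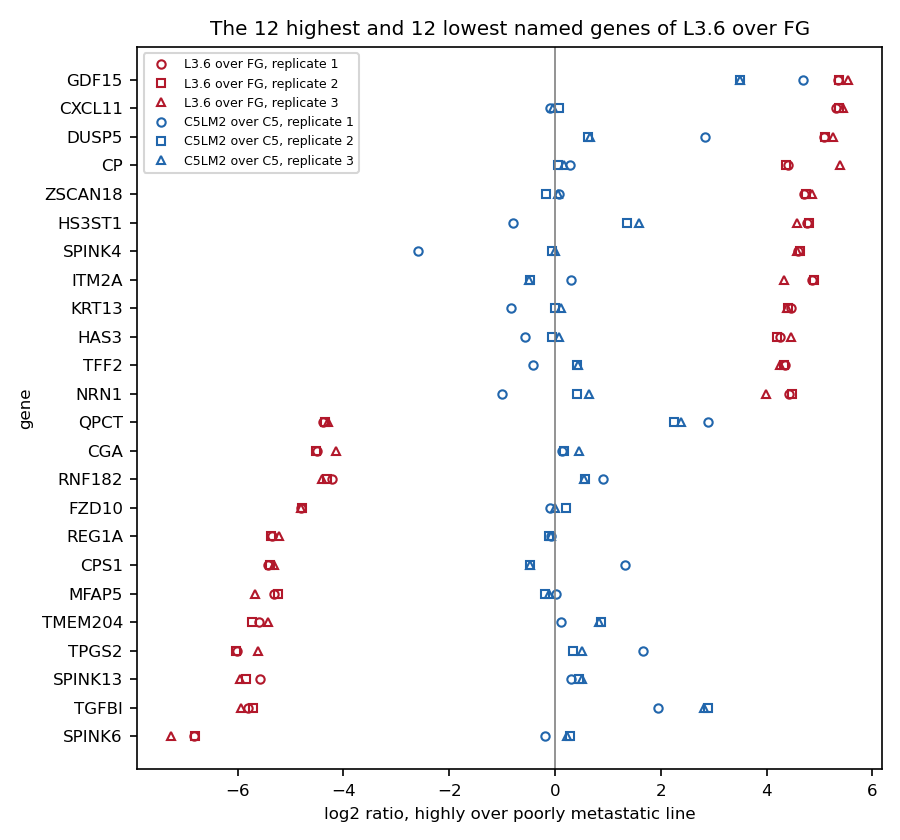
The horizontal axis gives the log2 ratio of the highly over the poorly metastatic line for the 24 genes named by rule in L3.6 over FG, one gene per line, with red marks for the 3 arrays of L3.6 over FG and blue marks for the 3 arrays of C5LM2 over C5. The red marks of GDF15 lie between 5.35 and 5.54, and its blue marks, between 3.49 and 4.69, are the farthest to the right of the blue marks.

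Counts of list members that rose or fell in L3.6 use the spread shared by both pairs, so they also reflect the scatter of the C5 pair. Genes of the hypoxia response were higher in L3.6 as a group. Of 30 tested members 8 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 ratio of 1.49. They included the prolyl hydroxylase EGLN3 (2.80), the disulphide oxidase ERO1A (2.45), ANKRD37 (2.37) and PPFIA4 (1.72). Limma's camera test with a preset correlation gave adjusted p = 1.37e-11 for this list, and adjusted p = 0.559 with an estimated correlation. With an estimated correlation the test recovered 0 of 3 shifted lists in simulated data. A call lost with it, here and below, therefore does not decide. Those data do not show whether calls with the preset correlation hold where the members of a list vary together. Among the lists that passed in L3.6, the estimated correlation ran from -0.0497 (mucins) to 0.891 (proliferation). The p-values with the preset correlation, here and below, may therefore be too low for some lists. Glycolysis genes shifted the same way by a median of 0.30, and 2 of 20 members rose (5 adjusted over the list alone), the enolase ENO2 (1.78) and the kinase PGK1 (1.39). Their camera adjusted p was 0.0194, against adjusted p = 0.704 with an estimated correlation and 0.0647 on the scanner software's own signals.

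NF-kB cytokines and chemokines were higher, with 12 of 33 members up and 1 down (15 and 3 adjusted over the list alone) and a median of 1.40. Besides CXCL11, the granulocyte growth factor CSF3 (3.83), the chemokine CXCL10 (2.69) and the mitochondrial superoxide dismutase SOD2 (3.56) rose (camera adjusted p = 1.21e-07, and adjusted p = 0.704 with an estimated correlation). Antigen presentation genes were higher in 6 of 24 members and lower in 0 (9 and 0 adjusted over the list alone), with a median of 1.05. The MHC class II chains HLA-DRA (4.22), HLA-DPB1 (3.67) and HLA-DRB1 (3.45) rose, and the invariant chain CD74 was at least 4.71-fold higher, being not well above background in FG (camera adjusted p = 6.97e-08, and adjusted p = 0.857 with an estimated correlation).

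Mucins and trefoil factors, the secreted components of epithelial mucus, rose in 5 of 17 members and fell in 0 (6 and 0 adjusted over the list alone). MUC2 stood at 3.99, TFF1 at 2.88 and AGR3 at 2.55, the last with FG above background on 1 of 3 arrays. The list's median was 0.38 and its camera adjusted p 0.00202, against adjusted p = 0.704 with an estimated correlation and 0.121 with median centring in place of loess. Its median minus that of all genes was 0.357, and 0.353 with median centring. In the CEA family of cell-surface glycoproteins 2 of 7 members rose (3 adjusted over the list alone), CEACAM5 (1.91) and CEACAM7 (1.26, FG above background on 1 of 3 arrays). Its median was 1.14 (camera adjusted p = 0.0282, adjusted p = 0.857 with an estimated correlation, and 0.188 with median centring). The family's median minus that of all genes was 1.12, and 0.999 with median centring. Ribosomal protein genes shifted upwards by a median of 0.39 with 0 of 44 members past the threshold, also over the list alone (camera adjusted p = 0.00268, adjusted p = 0.857 with an estimated correlation, and 0.367 on the scanner software's own signals).

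Proliferation genes had lower ratios in L3.6, with negative values for 38 of 40 members and a median of -0.69, although 0 passed the threshold singly, also over the list alone (camera adjusted p = 3.91e-06, and adjusted p = 0.939 with an estimated correlation). NRF2 and xenobiotic metabolism genes had a median of -0.94. Of 29 members 2 fell (7 adjusted over the list alone), the vitamin D hydroxylase CYP24A1 (-1.92) and the aldehyde dehydrogenase ALDH1A1 (-2.77), with camera adjusted p = 7.43e-05 and adjusted p = 0.704 with an estimated correlation. DNA repair genes had a median of -0.43, and 1 of 30 fell (4 adjusted over the list alone), the alkyl transferase MGMT (-3.32), with camera adjusted p = 0.00103 and adjusted p = 0.857 with an estimated correlation.

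Groups often studied in metastasis went both ways. Of 36 matrix metalloproteinase and plasminogen genes 6 rose and 3 fell (11 and 6 adjusted over the list alone), among them MMP1 (3.17), the urokinase PLAU (3.35), MMP10 (1.65, FG above background on 1 of 3 arrays) and MMP9 (-2.07), with camera adjusted p = 0.526 for the list and adjusted p = 0.957 with an estimated correlation. Of 35 metastasis genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), among them the secreted phosphoprotein SPP1 (3.19), TWIST1 (1.92) and the adhesion molecule L1CAM (-1.95). MACC1 was at least 3.28-fold higher, being not well above background in FG (camera adjusted p = 0.793 for the list, and adjusted p = 0.957 with an estimated correlation). Markers of other cell types did not pass camera, whose adjusted p was 0.626 for fibroblast, 0.627 for endothelial and 0.893 for haematopoietic markers, and adjusted p with an estimated correlation was 0.939, 0.939 and 0.957. Fibroblast markers, with a median of 0.04 and 7 of 14 members negative, were called lower by fry (adjusted p = 0.0481), which tests whether the members of a list move one way on balance and does not set them against other genes. Of the lists that passed camera, fry called hypoxia, mucin and NRF2 genes (adjusted p = 0.0325 each), glycolysis genes and NF-kB cytokines (0.0340 each). It did not call DNA repair (adjusted p = 0.104), antigen presentation (0.123), the CEA family (0.123), ribosomal proteins (0.139) or proliferation (0.325).

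**Figure D2:**
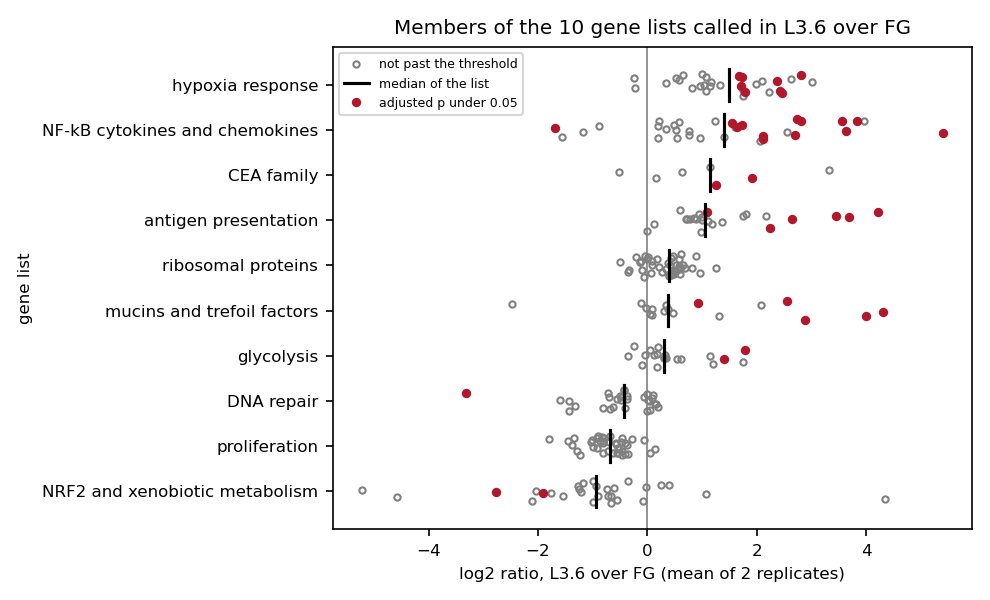
Each circle is one tested member of the 10 gene lists that passed camera in L3.6 over FG, placed by its log2 ratio (mean of 2 replicates) on the horizontal axis, with filled circles for adjusted p under 0.05 and a bar at the list's median. The medians run from 1.49 for the hypoxia response to -0.94 for NRF2 and xenobiotic metabolism. All 10 calls are lost with an estimated correlation, a test that recovered 0 of 3 shifted lists in simulated data. Those data do not show whether calls with the preset correlation hold where the members of a list vary together.

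These counts came from limma with a spread shared by both pairs and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The named genes had to pass with that same spread, so their choice also depended on the scatter of the C5 pair. Of the 790 genes, 661 also changed at least 2-fold (342 up and 319 down), and on the arrays the log2 ratios of replicate 3 correlated with the mean of replicates 1 and 2 at r = 0.974 across genes, which are not independent replicates. The count depended on which pair gave the spread: it was 0 without replicate 3 of L3.6 over FG, where the spread comes from the C5 pair alone, and 14370 without replicate 1 of C5LM2 over C5, where it comes from the FG pair alone. It was also 0 on the values of the authors' series table, 350 with both lines above background, 470 on the scanner software's processed signals and 491 with no filter on dim probes, against 1836 with median centring in place of loess (1437 up and 399 down, after a shift of the median of all genes by 0.35), 5050 with the slide as a random block, 17218 within the slide that held both pairs and 6292 with the 6 arrays as separate replicates.

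Between C5LM2 and C5 no gene passed the limma threshold, but some had large ratios of one sign on all 3 arrays. The ones named here were chosen after their values were seen, as those at least 2-fold the same way both in replicate 1 and in the mean of replicates 2 and 3. BEX2 stood at 5.78 ± 0.73 (SD, n = 2), the matricellular protein CCN3 at 4.95 ± 0.28, the stearoyl-CoA desaturase SCD at 4.48 ± 0.73, GPNMB at 4.48 ± 1.30, GDF15 at 4.09 ± 0.85, CCN5 at 3.65 ± 0.35 and CLGN at 3.57 ± 0.28. IL13RA2, a decoy receptor for interleukin-13, was at least 28.6-fold higher, being not well above background in C5. On the other side stood BAMBI, a pseudoreceptor that dampens TGF-beta signalling (-4.65 ± 1.76), the heparan endosulphatase SULF2 (-4.35 ± 2.59), RFLNA (-4.01 ± 1.20), the immediate early factor EGR1 (-4.83 ± 3.74), GNG4 (-2.83 ± 0.58), the ERK phosphatase DUSP6 (-2.76 ± 0.28) and SCD5 (-2.61 ± 0.31), as well as PDE9A, which was 7.97-fold lower. One sign on all 3 arrays was part of the choice of these genes, and their limma adjusted p ran from 0.108 to 0.292. In all, 0 of 19013 genes passed, 2612 had an unadjusted p under 0.05, and 0 passed with the pair fitted alone, but 882 (854 up and 28 down) with median centring in place of loess.

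The log2 ratios of replicate 1 and of the mean of replicates 2 and 3 of C5LM2 over C5 had a correlation of -0.0248 across genes. At least 2-fold ratios of the same sign in both were found for 366 genes on the higher side, against 215 for independent replicates, and for 71 on the lower side, against 75.6. The lower genes named above were chosen from these 71, a number no higher than independent replicates would give. Another 475 genes changed at least 2-fold in opposite directions, against 262. THBD, the thrombin receptor thrombomodulin, had a log2 ratio of -4.48 in replicate 1 and a mean of 6.24 in replicates 2 and 3. IGFBP7 had 4.04 and -4.58.

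**Figure D3:**
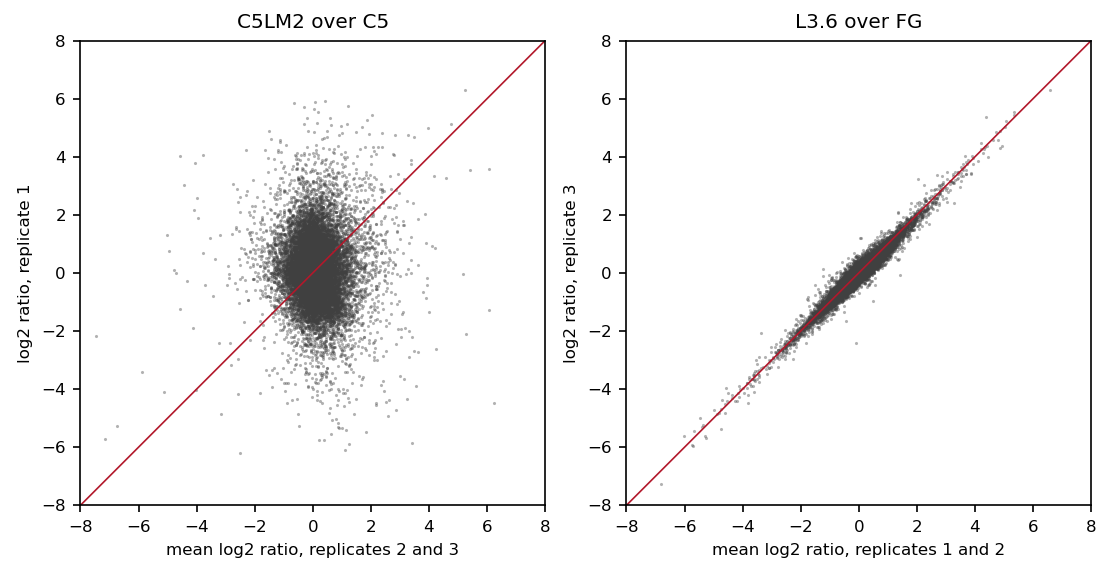
Each point is one gene, with its mean log2 ratio over the couple of arrays on one slide on the horizontal axis and its log2 ratio on the remaining array on the vertical axis, for C5LM2 over C5 (left) and L3.6 over FG (right). The points of L3.6 over FG follow the diagonal (r = 0.974), and those of C5LM2 over C5 do not (r = -0.0248).

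As groups, 9 lists passed camera in C5LM2, and none with an estimated correlation, where the adjusted p was 0.877 for proliferation and 0.776 for each of the other 8. None passed fry either, whose adjusted p ran from 0.0591 for cholesterol and mesenchymal genes to 0.581 for proliferation genes. Cholesterol and fatty acid synthesis genes had the lowest camera p, with a median of 0.82 and positive values in 29 of 31 members. None passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 3.31e-08, and adjusted p = 0.776 with an estimated correlation). Unfolded protein and ATF4 response genes (median 0.60, 7 of 30 up adjusted over the list alone, camera adjusted p = 0.000191), mesenchymal genes (0.71, 5 of 33, 0.00903) and integrins (0.52, 4 of 18, 0.0186) shifted the same way. The last 2 lists lost the camera call with median centring in place of loess (adjusted p = 0.598 and 0.364). Their medians minus that of all genes did not shrink, at 0.67 and 0.48, against 0.80 and 0.50 with median centring. Cancer-testis antigens had a median of 0.93 (1 of 17, 0.0298). Their camera direction turned with median centring (adjusted p = 0.779), and they no longer passed camera without background correction (adjusted p = 0.0529). Their median minus that of all genes stayed as large, at 0.893, against 1.03 with median centring and 0.886 without background correction. Without replicate 1 the camera direction also turned, and the median was 0.17. Epithelial junction genes had a median of -0.65 (1 of 35 down adjusted over the list alone, camera adjusted p = 0.000385), but without replicate 1 the median was -0.00114 and the call was lost (adjusted p = 0.659). NF-kB cytokines had a median of -0.46 (0 of 25, 0.0199) and were still called lower with median centring (adjusted p = 0.00123), but not without replicate 1 (median -0.29, adjusted p = 0.515). Proliferation genes (-0.42, 0 of 40, 9.04e-05) and DNA repair genes (-0.30, 0 of 29, 0.00559) also shifted lower, but with median centring they no longer passed camera (adjusted p = 0.417 and 0.377). Their medians minus that of all genes shrank from -0.46 and -0.34 to -0.13 and -0.07 with median centring. Without replicate 1, where the lone remaining sample is assumed to vary like the other pair, 10763 genes (6221 up and 4542 down) and 15 lists passed, none of these lists with an estimated correlation (adjusted p = 0.619 for each). The lowest camera p was then that of proliferation genes (median -1.05, adjusted p = 7.13e-19), the medians of cholesterol genes, mesenchymal genes and integrins were 0.53, 0.41 and 0.80, and type I interferon genes went from -0.18 to 1.22 (adjusted p = 2.83e-09). With the slide as a random block the count was 1459 (1045 up and 414 down), within the slide that held both pairs 16027, and with the 6 arrays as separate replicates 3040 (2007 up and 1033 down).

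Among the named genes that passed and have an exact size, the pairs differed most in TGFBI. Its log2 ratio was 2.40 in the C5 pair and -5.84 in the FG pair, a difference of 8.24 ± 0.43 (SE). Differences of the same sign were found for SPINK6 (7.07), the Wnt-induced CCN5 (6.58) and LYNX1 (6.04). QPCT, TPGS2 and TMEM204, with L3.6 not well above background on any array, and SPINK13, with C5 not above it, also passed on this side and have no exact size. On the other side were DUSP6, at -2.76 in the C5 pair and 2.98 in the FG pair (difference -5.75 ± 0.33, SE), CXCL11 (-5.43), HLA-DRA (-5.00), KRT13 (-4.79), ZSCAN18 (-4.78), CP (-4.69) and HAS3 (-4.62), and ITM2A with no exact size, since FG was not well above background. For SPINK6, CXCL11, HLA-DRA, KRT13 and ZSCAN18 neither C5 nor C5LM2 was well above background on all 3 arrays, so the ratio in the C5 pair is one of dim signals. For each of these 16 genes the 3 arrays of one pair did not overlap those of the other, as the rule for naming required. Their limma adjusted p ran from 0.0410 to 0.0489. In all, 161 of 21064 genes passed the limma test of the difference, 98 with the higher ratio in the C5 pair and 63 in the FG pair. The count was 0 without replicate 3 of L3.6 over FG, where the spread comes from the C5 pair alone, 0 without background correction, 0 on the scanner software's processed signals and 0 on the authors' series table. It was also 0 with no filter on dim probes, with all lines above background and with a variance prior from tested genes alone, and 12675 without replicate 1 of C5LM2 over C5. It was 669 (254 and 415) with median centring, 17187 within the slide that held both pairs and 4769 with the 6 arrays as separate replicates. With the slide as a random block it was 13815, and with the replicate number as a block 1965.

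By limma 0 genes passed in the same direction in both pairs, as none passed in the C5 pair. This count was 119 with median centring in place of loess, with 26 genes passing in opposite directions. It was 354 with the slide as a random block (216 opposite) and 802 with the 6 arrays as separate replicates (493 opposite). Within the slide that held both pairs it was 7910 (5751 opposite). Across 17996 genes tested in both pairs the mean log2 ratios had a Pearson r of 0.0468 and a Spearman rho of 0.0552, and genes are not independent replicates. With replicates 2 and 3 of C5LM2 over C5 set against replicates 1 and 2 of L3.6 over FG, on one slide, r was 0.126 and rho 0.160, and against replicate 3 on another slide r was 0.112 and rho 0.137. With replicate 1 of C5LM2 over C5 r was -0.00189 and -0.0355.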

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

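The 4 tests on replicate 1 of C5LM2 over C5 were chosen only after its values were seen, and the 2 counts of sample splits were planned.

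The ratio of the highly over the poorly metastatic line differed between the pairs for 34 genes named by the rule, by limma's test of the difference. Given as the C5 pair minus the FG pair on the log2 scale, these were on the negative side DUSP6 (-5.75), CXCL11 (-5.43), HLA-DRA (-5.00), KRT13 (-4.79), ZSCAN18 (-4.78), CP (-4.69), ITM2A (-4.68), HAS3 (-4.62), TFF2 (-4.29), CSF3 (-4.01), MUC2 (-3.90), HLA-DPB1 (-3.89), HLA-DRB1 (-3.81), CXCL10 (-2.67), CD74 (-2.51) and the Wnt antagonist DKK4 (-2.28). On the positive side were TGFBI (8.24), SPINK6 (7.07), QPCT (6.93), TPGS2 (6.87), CCN5 (6.58), SPINK13 (6.22), LYNX1 (6.04), TMEM204 (6.02), MFAP5 (5.41), the fatty acid desaturase FADS2 (5.22), REG1A (5.21), RNF182 (5.07), FZD10 (4.81), CGA (4.55), LY6D (3.57), MAGEB2 (2.98), fibronectin FN1 (2.96) and L1CAM (2.53). For QPCT, TPGS2, TMEM204, ITM2A, CD74 and DKK4 one line of the FG pair, and for SPINK13, FN1 and TMEM204 C5, was not well above background on any array, so these are fitted values with no exact size. For CXCL11, HLA-DRA, KRT13, ZSCAN18, CSF3, HLA-DPB1, CXCL10, CD74, DKK4, SPINK6, MFAP5, REG1A, FZD10, CGA and MAGEB2 neither C5 nor C5LM2 was well above background on all 3 arrays, so the C5 ratio is one of dim signals.

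Among gene lists, camera on the same contrast gave lower ratios in the C5 pair for 10 lists. Their median differences were -1.93 for the pancreatic classical subtype, -1.71 for NF-kB cytokines, -1.56 for the CEA family, -1.45 for the hypoxia response, -1.27 for antigen presentation, -0.93 for mucins, -0.83 for epithelial junctions, -0.56 for receptor tyrosine kinases, -0.47 for glycolysis and -0.21 for ribosomal proteins. In the C5 pair only 5 of the 16 members of the classical subtype and 3 of the 7 of the CEA family were tested, so these 2 medians rest mostly on dim C5 signals. Without replicate 1 of C5LM2 over C5 the medians were -0.28 for epithelial junctions, -0.33 for antigen presentation, -0.49 for the CEA family, -1.12 for the classical subtype and -0.29 for receptor tyrosine kinases, and the calls of epithelial junctions (adjusted p = 0.0634), the CEA family (0.120) and ribosomal proteins (0.132) were lost. Higher ratios were called for NRF2 and xenobiotic metabolism (0.44), cholesterol and fatty acid synthesis (0.54) and the unfolded protein response (0.62). The camera adjusted p of these 13 lists ran from 5.23e-09 to 0.0476, and adjusted p with an estimated correlation from 0.533 to 0.873.

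The real grouping gave 161 genes whose change differs between the pairs, and the highest of the other splits of the 4 samples gave 0, so 1 of 3 splits gave as many. With the 6 arrays as separate replicates the real grouping gave 4769 genes and the highest other split 0, so 1 of 10 splits gave as many. Both sets of splits are too few for a share under 0.05. The other splits also mix the pairs within a group, so that the difference between the pairs enters the spread and lowers their counts. The counts of 0 therefore do not decide.

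Replicate 1 of C5LM2 over C5 stood apart from replicates 2 and 3, and its spike-in probes, which no comparison used, had a median log2 ratio of -2.02, against 0.40 on both other arrays of the pair. An exchange of its dyes was argued against by a correlation of -0.0539 with replicate 2, where an exchange needs a strongly negative one. The use of another slide as such was argued against by r = 0.965 for replicate 3 of L3.6 over FG, which also lay on another slide. That FG array had median spike-in signals of only 4.16 in Cy3 and 4.09 in Cy5. Of its spike-in spots 10.9% and 11.25% were well above background, against 100% on replicate 1 of C5LM2 over C5. In this respect it is not a like control. Replicate 1 of C5LM2 over C5 had 705 genes at least 8-fold brighter in Cy3 than replicates 2 and 3, against 160 in Cy5. It had 340 at least 8-fold dimmer in Cy3, against 67 in Cy5. These counts were made after normalisation, which rescales a weak channel, so they do not decide on degraded or poorly labelled Cy3 RNA. What stays open is that its Cy3 RNA may differ from the C5 RNA of the other arrays. Its Cy3 signals had a mean r of 0.795 with C5 and 0.844 with FG, a difference of -0.0496. Their mean r was 0.826 with C5LM2 and 0.829 with L3.6, so C5 was the line they matched least. Its Cy5 signals had a mean r of 0.920 with C5LM2 and 0.895 with C5, against 0.830 with FG and 0.814 with L3.6. Arrays of FG or L3.6 on different slides correlated at 0.985 to 0.988. Another culture state of C5 and a fault of that slide alone were not tested, and the deviations of both channels correlated at r = 0.508, so Cy5 was not spared.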

How the results depend on the processing

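The settings chosen after seeing the data were the averaging of arrays on one slide behind the main counts, the averaging of FG replicates 1 and 2 alone, and a variance prior from tested genes alone. The 6 arrays as separate replicates were the design as first fixed, listed as an alternative once the averaging was adopted, and the others were planned. The main counts were 0 genes for the C5 pair, 790 for the FG pair, 161 for the difference and 0 the same way in both, with r = 0.0468 between the pairs and 9 and 10 gene lists. Over the settings, 3015 calls of named genes were the same, 221 stronger, 394 weaker and 0 reversed. A reversal is a changed sign, which settings that alter only the variance model cannot give. For the genes of the C5 pair, the same means still short of the threshold. For the difference only 16 genes were followed, and genes that a setting did not test were not counted, such as 11 of these 16 with both lines above background. Signal over background limits the dim genes, which have only a bound where a line was not above it.

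The FG count was 470 on the scanner software's processed signals, 0 on the series table's values, 491 with no filter on dim probes, 350 with both lines above background, 14370 with each pair fitted alone and 1356 without a trend. The difference count was 85 with an offset of 10 and 264 without a trend. It was 0 without background correction, on the processed signals, on the series table, with no filter, with both lines above background, and with the prior from tested genes alone, where FG had 621. Median centring gave 882 (854 up, 28 down), 1836 (1437, 399) and 669 (254, 415) for C5, FG and the difference, 119 the same way and r = 0.143. The slide as a random block gave 1459, 5050, 13815, 354 and r = 0.146. Only the slide with both pairs gave 16027, 17218, 17187 and 7910, and the slide as a fixed block 17187 for the difference; there the spread is that of arrays on one slide. The 6 arrays as separate replicates gave 3040, 6292, 4769 and 802, and averaging FG replicates 1 and 2 alone 989, 2385, 1820 and 133.

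The replicate number as a block gave 1965 for the difference (1184 and 781). Deviations of same-numbered arrays correlated at 0.0632, -0.0710 and 0.0835, and those of differently numbered arrays at -0.0824 to 0.0805. Arrays of one pair on one slide nearly coincided (r = 0.992 in the C5 pair and 0.995 in the FG pair). These values are therefore not independent of each other and cannot show whether the numbers pair the samples. For lists, C5 had 17 with no filter on dim probes, 0 with an estimated correlation and 0 with fry, and FG had 0 with an estimated correlation and 6 with fry, 1 of them the fibroblast markers.

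Leaving out each array in turn gave 0 to 10763 genes for C5, 0 to 14370 for FG, 0 to 12675 for the difference, 0 to 4655 the same way, r from 0.0466 to 0.120, 9 to 15 lists for C5 and 10 to 12 for FG. The high ends came without replicate 1 of C5LM2 over C5, and the FG and difference counts of 0 without replicate 3 of L3.6 over FG. Without either array its pair has 1 sample left and the spread comes from the other pair alone, so these counts do not test the ratios themselves. The requirement of a 2-fold change gave no list value, and each pair fitted alone no difference.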

Other observations

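The tests on copy number and on the slide were planned before their results were seen, the test on dye bias was chosen after, and the genes on all 6 arrays were selected after their values were seen.

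Keratins and genes of the pancreatic basal subtype changed both ways in L3.6 over FG. KRT5, a keratin of basal epithelium, had a log2 ratio of -1.90 and KRT13 one of 4.40. Of 18 tested keratins 1 rose and 2 fell (2 and 4 adjusted over the list alone), and camera gave adjusted p = 0.188 for the list and adjusted p = 0.939 with an estimated correlation. Of 21 basal subtype genes 1 rose and 3 fell, also over the list alone: LY6D stood at -3.65 and the serpins SERPINB3 and SERPINB4 at -2.66 and -2.47, while SPRR3 was at least 1.74-fold higher, being not well above background in FG (camera adjusted p = 0.225, and adjusted p = 0.939 with an estimated correlation). Among 33 mesenchymal genes 2 rose and 2 fell (5 and 7 adjusted over the list alone), with the collagen cross-linker LOX at 2.41 and fibronectin FN1 at -2.55 (camera adjusted p = 0.943, and adjusted p = 0.957 with an estimated correlation). Of 25 stem cell genes 0 rose and 4 fell (5 and 5 adjusted over the list alone), the intermediate filament NES at -1.81, ALDH1A1 at -2.77, DCLK1 at -0.72 and NANOG at -0.71 (camera adjusted p = 0.928, and adjusted p = 0.957 with an estimated correlation). Of 29 unfolded protein and ATF4 response genes 1 rose and 2 fell, also over the list alone, the lipoprotein receptor VLDLR (2.11) and both subunits of an amino acid transporter, SLC7A5 (-2.11) and SLC3A2 (-1.86), with camera adjusted p = 0.928 and adjusted p = 0.957 with an estimated correlation.

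At least 2-fold ratios of one direction on all 6 arrays were found for 54 genes on the higher and 11 on the lower side, against 14.5 and 3.15 for independent pairs among 17996 genes. Higher on all 6 were GDF15, the lymphangiogenic factor VEGFC, with mean log2 ratios of 3.43 in the C5 pair and 2.66 in the FG pair, LOXL1 (3.20 and 2.08), VLDLR (1.98 and 2.11) and RRAGD (2.71 and 2.21). Lower were BAMBI (-4.65 and -3.78), galanin GAL (-1.74 and -3.13), AKR1C1 (-2.67 and -2.10) and clusterin CLU (-1.53 and -1.82). None of these passed in the C5 pair. Since no dyes were swapped, gene-specific dye bias may account for part of this: same-way genes were 3.67 times their expected number, but genes going opposite ways in the pairs, which such a bias cannot add, were 2.10 times theirs (38 against 18.1). The excess of one over the other leaves dye bias and a shared difference open, and they cannot be told apart without arrays of the other dye orientation.

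Changes of L3.6 over FG were clustered along chromosomes. Of 19411 windows of 20 neighbouring genes, 1939 had a median log2 ratio beyond 0.4, 844 higher and 1095 lower, against at most 195 in 1000 shuffles of the genes. The stretches with the most genes were on chromosome 9 from 4707 to 45453420 (hg18), with a median of 0.53 over 247 genes, and on chromosome 8 from 25341789 to 56955213, with -0.60 over 149 genes. An effect of the slide was argued against by r = 0.942 between the medians of all windows on the 2 slides. Over the windows beyond 0.4, chosen on the mean of the same 2 slides, r was 0.987. A difference in copy number between the lines may underlie these stretches, as a hypothesis; co-regulation of neighbouring genes was not excluded, the windows overlap, and no DNA was measured.

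In the C5 pair 2153 of 18385 such windows were beyond 0.4, 1795 higher and 358 lower, against at most 235 in 1000 shuffles, but the medians of all windows correlated between its replicates at 0.108, and those of the windows beyond 0.4 at 0.334. In the stretches with the most genes, replicate 1 had larger medians than the mean of replicates 2 and 3. They were 0.896 against 0.289 on chromosome X, 0.628 against 0.283 on chromosome 18 and -0.969 against -0.0432 on chromosome 8. Some smaller stretches went the other way, such as chromosome 5 from 87517484 to 106856956 (0.363 against 0.443). The authors' deposited lists of spots at least 10-fold brighter in Cy5 had 44 probes common to the 3 arrays of the C5 pair, 250 common to its replicates 2 and 3, and 190 common to the 3 arrays of the FG pair. The spots in all 6 lists came from 3 genes, MME, SLC6A15 and GDF15. The ratios used here were smaller for SLC6A15 (1.33 to 1.66 on the arrays of the FG pair) and for MME (0.92 to 1.37), neither gene being above background in FG.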
